A study of Mus musculus with 2 samples.

How the data were processed

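Bone marrow and bone chips of Lepr-Cre tdTomato reporter mice were digested separately for 25 min at 37 °C and then pooled, per the labels' protocols. Blood cells were depleted magnetically in 2 rounds, the first against lineage markers and the second against CD45 and cKit. Libraries were made from the remaining cells with a 10x Genomics Chromium 3′ v3.1 kit, which captures the polyadenylated ends of transcripts. Each of the 2 libraries, PBS and DOX, was pooled from 2 mice. Groups were taken from the treatment label.

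Reads were processed by the authors with Cell Ranger 7.2.0 against mm10, per the submitters' processing notes. The annotation release, the handling of introns and the settings of cell calling are not given in the sources used here. The deposited files used here list, per library, the filtered cell barcodes (16 bases and a suffix that was the same for every barcode) and the features (gene identifier, symbol and feature type). They hold text and no expression value. Counts per gene and cell were not analysed here, so depth per cell, filters on cells, doublets, clusters and expression could not be examined, and the comparisons fixed for them before the data were examined were not run.

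Barcodes were compared as exact 16-base sequences. Counts were given exact 95% Poisson intervals, and shares exact Clopper-Pearson intervals. These cover counting error only. The overlap expected by chance was the product of the numbers of barcodes divided by an assumed list size of 1000000 or 3000000. These sizes were set after the overlap was seen, and the list of the kit was not used here. Base composition, runs of shared barcodes in the sorted lists and pairs of similar barcodes were set against 10000 random subsets of each library of the same size as the shared set, without replacement (seed 11). Pairs of barcodes that differed at 1 base were counted within and between libraries and compared by an exact two-sided binomial test, given the number of possible pairs of each kind. Pairs that share a barcode are not independent. Barcodes found in both libraries stayed in both lists, so a pair holding such a barcode could count both within and between libraries. The barcode statistics were tested on simulated data, lists of 5000 and 4000 barcodes, in which 6 of 6 known quantities were recovered, counts exactly and the base share within 3 binomial SDs. The measure of shared 3′ sequence described next was tested on 4 simulated genes with copied ends of known length, and 4 of 4 percentages were recovered.

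Features were matched by identifier to the GENCODE M21 annotation of GRCm38, the assembly on which mm10 rests. Of 32285 Ensembl identifiers 50 were not matched. Gene lists were fixed before the data were examined. The rule for naming genes would have named, without expression values, only listed genes that were absent from the feature list or on several rows, and the reporter; the genes named beyond these were chosen after their values were seen. Shared 3′ sequence was measured as the percentage of 50-base words in the last 500 bases of a gene's transcripts that also occur in a transcript of another counted gene. Coding transcripts of the GENCODE basic set with a complete 3′ end were used. Other genes were searched in the GENCODE M21 transcripts, so the 50 unmatched identifiers and the tdTomato row could not be found as partners. Words of 30 and 90 bases and the last 300 bases were alternatives. The read length is not given in the sources used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.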

Results

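Droplet-based single-cell RNA sequencing of bone marrow and bone was compared between mice given doxorubicin, an anthracycline chemotherapy drug that acts on type II topoisomerases, and mice given phosphate-buffered saline (PBS) as the vehicle. The mice carried a Lepr-Cre driver with a Cre-dependent tdTomato reporter. Lepr encodes the leptin receptor, a marker of mesenchymal stem and progenitor cells of the marrow. Doxorubicin (5 mg/kg) or PBS was injected into a vein 4 times at intervals of 1 week, starting at 8 to 10 weeks of age, and tissue was taken 8 weeks after treatment. There was 1 library per group, each pooled from 2 female mice. The series asked how chemotherapy affects skeletal progenitors. The values analysed here were the list of cell barcodes of each library and the list of genes against which reads were counted. Expression values per cell were not analysed here, so the report gives no gene level, no cell type share and no difference in expression between doxorubicin and PBS. The number of RNA molecules per cell is for the same reason unknown here.

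The PBS library held 16251 cell barcodes and the DOX library held 12958, which is 0.797-fold as many in DOX as in PBS. The exact 95% Poisson interval was 16002 to 16503 for PBS and 12736 to 13183 for DOX. The exact 95% interval of the ratio was 0.779 to 0.816. These intervals cover counting error only. With 1 pooled library per group the difference has no replicate check and no test between treatments was possible. The number of barcodes also depends on how many cells were loaded, on the depletion of blood cells and on cell calling. It is therefore no measure of how many non-hematopoietic cells the marrow held.

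The DOX and PBS libraries had 1705 barcodes in common, with an exact 95% Poisson interval of 1625 to 1788. They made up 10.5% of the PBS barcodes (exact Clopper-Pearson 95% interval 10.02% to 10.97%) and 13.2% of the DOX barcodes (12.6% to 13.8%). Separate droplet runs draw their barcodes from one list supplied with the beads, so some overlap arises by chance. An assumed list of 1000000 equally frequent barcodes would give 211 shared barcodes, and one of 3000000 would give 70.2. The observed overlap was 8.10 and 24.3 times these values. It is the overlap that an evenly used list of 123508 barcodes would give. Without the shared barcodes the PBS library held 14546 and the DOX library 11253, a ratio of 0.774. Taking the same number from both libraries lowers the ratio whatever these barcodes are, because DOX is the smaller library.

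Shared barcodes differed in base composition from those in 1 library only. G made up 22.2% of their bases, against 24.7% in barcodes of the PBS library alone and 24.9% in those of the DOX library alone. Among 10000 random subsets of the same size, the share of G ranged from 23.6% to 25.5% in PBS and from 23.6% to 25.4% in DOX, so the shared set lay below every subset drawn from either library. C made up 27.2% of the bases of shared barcodes, above the highest random subset of PBS (26.1%) and of DOX (25.8%). A and T lay within the range of the random subsets.

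**Figure D1:**
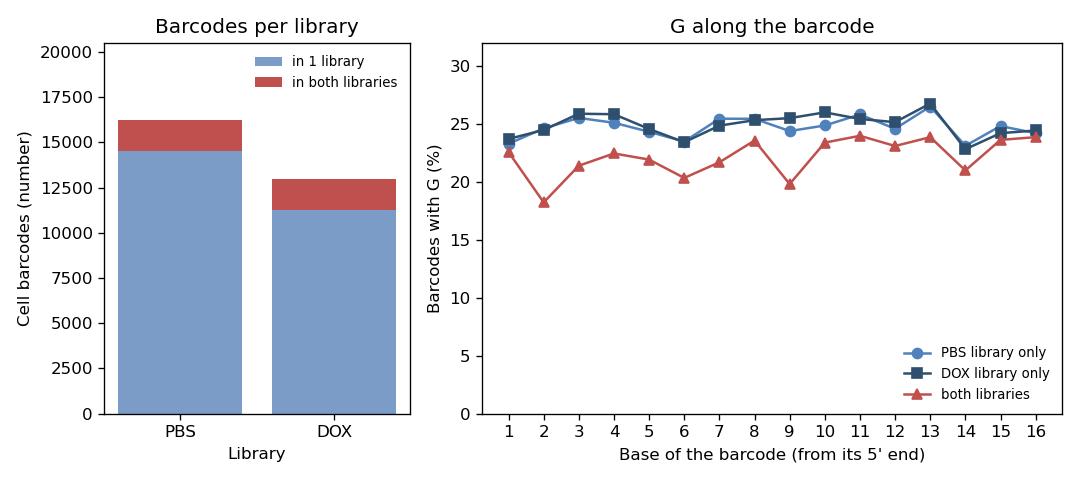
The left panel plots the number of cell barcodes per library as stacked bars, with barcodes found in both libraries (1705) on top of those found in 1 library (14546 in PBS and 11253 in DOX). The right panel plots the percentage of barcodes with G at each of the 16 bases, counted from the 5′ end. Its lines stand for barcodes of the PBS library alone, of the DOX library alone and of both. The shared set is the lowest at every base. The gap is widest at base 2 (18.2% against 24.6% in PBS and 24.5% in DOX). It is narrowest at base 16 (23.9% against 24.2% and 24.4%).

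Barcodes that differed at 1 base only were rare. There were 2 such pairs within the libraries, 1 in PBS and 1 in DOX, and 1 pair between them. The rate per possible pair was 1.95 times as high within as between libraries (exact two-sided binomial test, p = 1). That test compares barcode sequences and not treatments. With 3 pairs in all, the smallest p it allows is 0.12, so no excess of any size could have passed 0.05. Pairs at a distance of 2 bases or less numbered 1899 within and 1846 between libraries, so the rarity holds for 1 base only. How many pairs chance would give at either distance was not computed.

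The DOX and PBS libraries were counted against the same 32286 features, identical in all rows. The last feature was the tdTomato reporter, so reporter transcripts had a row in both libraries beside the endogenous Lepr gene. The sequence behind that row is not given in the sources used here. How much of the 3′ end of the reporter transcript it covers is therefore unknown. No row of the list was named Cre, WPRE or EGFP. The other 32285 features carried mouse Ensembl gene identifiers, of which 32235 were matched in the GENCODE M21 annotation of GRCm38. By that annotation 21702 were protein-coding genes, 9830 were long noncoding RNA genes and 697 were immunoglobulin or T cell receptor segments. The mitochondrial genome contributed 13 genes. In the list, 38 symbols stood on more than 1 row.

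Of 249 genes in the 28 lists fixed for this tissue and treatment, all 249 had 1 row each. The lists comprised 16 sets of cell type markers and 12 sets of pathway genes. The markers covered mesenchymal progenitors, bone, cartilage, fibroblast, pericyte, endothelial and Schwann cells, together with the blood lineages that the depletion was meant to remove. The pathway sets covered, among others, niche factors, adipogenic and osteogenic genes, p53 targets, senescence and interferon genes. Lepr (ENSMUSG00000057722) lies on chromosome 4 at 101717404 to 101815352 on the plus strand. Cxcl12 (ENSMUSG00000061353), a chemokine that retains blood stem cells in the marrow, lies on chromosome 6 at 117168535 to 117181367 on the plus strand. Top2b (ENSMUSG00000017485), one of the type II topoisomerases, lies on chromosome 14 at 16365179 to 16435462 on the plus strand. Coordinates are from GENCODE M21 on GRCm38. These 3 genes were chosen after the list was seen, Lepr and Top2b for the genotype and the drug.

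For 6 of the 249 genes, at least 50% of the 50-base words at their 3′ ends also occurred in transcripts of other counted genes. The other genes were searched in GENCODE M21 only, which leaves out tdTomato and the 50 unmatched identifiers. Part of the reads from a shared end could match another gene, and how such reads were counted was not examined. The words came from the last 500 bases of every transcript used, pooled per gene. A gene with several different ends can therefore share a whole end and stay below 50% of these words. The osteocalcin genes Bglap and Bglap2, products of osteoblasts, shared 74.7% and 88.2% of these words and lie next to one another on chromosome 3 (Bglap at 88383501 to 88384464, Bglap2 at 88377736 to 88378699, both on the minus strand). Among the erythroid markers the alpha-globin gene Hba-a1 shared 88.9%, mainly with Hba-a2, and the beta-globin genes Hbb-bs and Hbb-bt shared 64.7% and 64.5%, mainly with one another. The platelet glycoprotein gene Gp1bb shared 59.2%, mainly with Sept5, whose exons it overlaps on the same strand of chromosome 16. In the last 300 bases the threshold was passed by 3 genes rather than 6. In all, 24 of the 249 genes shared at least 1 word. The highest below the threshold were the monocyte marker Ly6c2 at 34.8%, the B cell precursor marker Vpreb1 at 33.9%, the endothelial marker Ly6c1 at 26.3%, the myeloid marker Lyz2 at 16.9% and the interferon-induced gene Ifit3 at 14.9%. Ly6c2 and Ly6c1 shared mainly with one another. Their pooled words numbered 733 and 1466, against 451 for Lyz2, so pooling may have lowered their percentages. Lepr, Cxcl12 and Kitl, the gene for stem cell factor, shared 0%. The 6 genes that passed the 50% threshold were in the osteogenic, bone marker, erythroid and megakaryocyte lists only. No gene of any other list passed it, which includes the mesenchymal progenitor, niche factor, p53 target and senescence lists.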

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

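The planned settings for barcode numbers and overlap could hardly move them, since every barcode was distinct within its library and 1 pair per library and 1 between them differed at 1 base, so these values say nothing about stability. Distinct sequences numbered 16251 in PBS and 12958 in DOX, and merging barcodes that differ at 1 base left 16250 and 12957. Leaving out barcodes found in both libraries, chosen after seeing the data, lowered them to 14546 and 11253. The overlap was 1705 also when the last base was ignored. The rate ratio of near-identical pairs was 1.003 (exact binomial p = 0.935) at a distance of 2 bases or less. That setting had many more pairs (1899 within and 1846 between libraries). Pairs holding a barcode found in both libraries could count on both sides, however. This can draw the rates together, and the binomial test does not allow for it. At 1 base the rate ratio was 1.59 in PBS alone and 2.51 in DOX alone, each from 1 pair within and 1 between. The smallest exact binomial p possible there is 0.149 and 0.0812, so that neither these nor the 3 pairs of both libraries could pass 0.05. Ignoring case left 38 symbols on more than 1 row, and 32208 rows had a symbol of their own. The number of listed genes with a shared 3′ end was 8 with words of 30 bases, 6 with words of 90 bases and 3 in the last 300 bases; these settings too were chosen after seeing the data. Settings planned for cell classes and gene levels were not run, since counts per cell were not analysed here. No paired analysis was possible because each group has 1 library. Leaving out a replicate was impossible for the same reason.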

Other observations

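Tests of the longest run and of the share of G were chosen after the result was seen; the test of similar pairs was chosen before. The 1705 barcodes found in both the PBS and the DOX library are 8.10 times as many as an evenly used list of 1000000 barcodes would give. Against such a list of 3000000 they are 24.3 times as many. A copied stretch of one list is argued against, since the longest run of shared barcodes was 4 in each library, within the 3 to 8 of random placements in PBS and 3 to 9 in DOX. Families of similar barcodes that are common in the beads could give more similar pairs among shared barcodes than in random subsets. No such excess was seen. There were 13 pairs of shared barcodes that differed at 2 bases or fewer. Random subsets had a median of 12 (2 to 27) in PBS and of 13 (3 to 29) in DOX. These ranges are wide, so only a large excess over the subsets is argued against and a small one cannot be excluded. The subsets came from the same libraries. Families that hold shared and other barcodes alike would raise their pairs too, so the comparison cannot show such families. Barcodes carried from one library to the other by swapped sample indexes stay open: a carry-over at random would leave the share of G within that of random subsets, and it was 22.2%, below all of them, but barcodes with many molecules may be carried more often and could differ in composition, which needs the counts per barcode. Single barcodes that are over-represented in the beads were not tested as an explanation. Barcode sequences come from the beads and not from the cells, so the biology of the mice does not set them.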
